A study of Homo sapiens with 18 samples.

How the data were processed

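Human Th17 cells from 3 donors were sorted by IL-1RI, kept for 9 h in media, with IL-1b or with an anti-CD3/CD28 reagent, and sequenced as 18 libraries, 1 for each donor, population and treatment. Per the labels, the cells were held overnight in 1 nM IL-2 before the sort, RNA was isolated with a small-sample column kit, and libraries were made with a stranded total RNA kit. The authors aligned the reads with STAR 2.5.3a to GRCh38. The deposited table holds raw counts per gene symbol, without normalisation, 1 column for each library. The counting tool, its gene annotation, its strand setting and any filter were not stated in the labels.

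The table had 56505 gene symbols. XIST, related and Y-linked genes, 535 symbols, were removed before any other step, since the donors are persons, which left 55970. Each of the 18 columns was matched to a library by its donor, population and treatment, and 0 columns of values were left unmatched. Positions, strands and gene types came from GENCODE release 29 on GRCh38, where 54236 symbols matched 1 gene, 62 matched more than 1 and 1672 matched none (0.731% of the counts). Because the strand setting of the counting was not stated, values of genes that overlap others on either strand are less certain, as are those of genes with near-identical copies, and the text names the main cases, IL26 among them.

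Totals ran from 29.5 to 42.6 M counts per library, which leaves relative counting error small for all but genes with few counts. The 10 most abundant genes took 4.02 to 5.69% of a library, mitochondrial genes 1.62 to 4.38% and protein-coding genes 95.7 to 97.2%. Replication-dependent histone symbols took at most 0.00611% and RN7SK had 0 counts over all libraries. Such low values may reflect selection of poly(A) RNA or a limit of the counts to certain gene types, although the labels give a total RNA kit. Neither was tested, so changes of the histone list are uncertain. Among 18 pairs of libraries within a group, the lowest chi-square per degree of freedom over genes with a summed count of at least 20 was 36.1 and the highest 117, and 0 pairs had identical counts. IL1R1 was checked against the sort: its lowest level in the 9 IL-1RI+ libraries was 510 CPM and its highest in the 9 IL-1RI- libraries was 53.5 CPM.

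Genes were filtered with filterByExpr of edgeR 4.0.16 by group, which left 18201, and scaled with TMM. The test was the edgeR quasi-likelihood F test, two-sided, on all 18 libraries with a mean for each of the 6 groups and no donor term, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. It was made for 8 comparisons, namely IL-1b and anti-CD3/CD28 against media in each population, IL-1RI+ against IL-1RI- cells in media, IL-1b against anti-CD3/CD28 in IL-1RI+ cells, and the difference between populations in each response. Standard errors were taken from the log2 fold change and its F statistic, and CPM were computed on TMM-normalised library sizes. Software was R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0, and python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

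The donor numbers in the sample titles pair libraries across groups, since every donor gave 6 libraries. The pairing was checked on deviations from group means: over 45 pairs of libraries from the same donor in different groups the correlation ran from 0.480 to 0.833 (median 0.680), and over 90 pairs from different donors its median was -0.371 and its highest value -0.0813. The closest library of another group was from the same donor for 18 of 18 libraries, and the first 2 components of the deviations held 73.7% of their variance. The common dispersion was 0.115 without and 0.0178 with the donor in the model. The fit without the donor is the reported one and the fit with the donor as a block is the alternative, and blocked values stand beside the named genes and the camera list calls they change. Counts of list members are from the fit without the donor unless the block is named; with the block more members passed in many lists.

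The tests, comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes were named if they passed the threshold, had a mean of at least 5 CPM in a compared group and moved the same way in 3 of 3 donors. The 10 largest rises and falls were taken for IL-1b and anti-CD3/CD28 in IL-1RI+ cells and for the populations in media, and up to 5 each way for the other comparisons. IL26, the sort markers and the Th17 cytokine list were always named, and up to 4 called members of each list with a camera adjusted p under 0.05 or at least 3 called members. Unnamed loci, antisense, micro and intergenic RNAs, antigen receptor segments and genes with inherited copy-number or haplotype differences were not named under this rule. Genes chosen after their values were seen are outside it and are described as such. Lists covered Th17 cytokines and lineage genes, other cytokines, NF-kB, IL-1 family, immediate early, activation, STAT and interferon genes, glycolysis, ribosome biogenesis, cell cycle, cholesterol synthesis, ATF4 and unfolded protein responses, resting and memory cells, heat shock, histones and mitochondrial mRNAs. Further lists held markers of regulatory, Th1, Th2, follicular helper, MAIT, CD8 and gamma-delta T cells, innate lymphoid and NK cells, B cells, and monocytes and dendritic cells. A list of platelet and red cell markers had 1 of 10 members past the filter and was not tested.

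Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry, which asks whether the members of a list move on balance one way and does not compare them with other genes. For genes with 0 counts in a group a lower bound on the ratio was computed against 3 counts over the group, and for those with 1 to 3 counts an exact 95% counting interval was given. Overlap of comparisons that share media libraries was set against independent lists and against 20 simulations of unchanged groups.

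The alternatives were DESeq2 size factors or upper-quartile factors in edgeR, the DESeq2 test, no filter beyond 1 count, a filter of 5 CPM in 3 libraries, the donor as a block, the compared groups alone, a minimum log2 change of 1, and each donor and each library left out. Another removed 3902 mitochondrial, histone, ribosomal and small RNA genes, 2.47% of the counts in the median library. The DESeq2 test with the donor, the compared groups alone with the donor, leaving donors out of the block fit, camera with an estimated correlation and the donor, and camera without IL1R1 for the lists that hold it were added after seeing the data.

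The pipeline was tested on simulated data in 3 runs of 17871 to 17902 genes with known changes. For IL-1b in IL-1RI+ cells it recovered 42.6% of genes changed by a log2 of 1 and 69.9% of those changed by 2, with 0% of its calls on unchanged genes; with the donor block these were 58.5%, 85.0% and 3.87%. For the difference between populations it recovered 24.3% and 53.5% with 0% on unchanged genes, and with the block 46.0%, 72.9% and 5.87%. The simulated counts were drawn from the fit with the donor block, with the same donor effects in every group. The setting therefore favours the block, and these rates do not give the share of false calls in the real data.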

Results

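Gene expression was measured by RNA sequencing in 18 libraries of sorted human Th17 cells, the CD4 T helper cells that make IL-17. Blood cells from 3 donors were sorted as CCR6+ CD161+ CCR4+ CXCR3- cells and divided by IL-1RI, the signalling receptor for IL-1b, into IL-1RI+ and IL-1RI- cells. Each population was then kept for 9 h in media, with 100 ng/ml IL-1b, or with 5 µl/ml of an anti-CD3/CD28 reagent, which stimulates T cells through their antigen receptor and CD28. This gave 6 groups of 3 libraries, 1 library from each donor. Total counts ranged from 29.5 to 42.6 M (mega) per library, with a median of 37.0 M. The group means (± SD, n = 3) of IL-1RI+ cells were 37.5 ± 2.14 M in media, 39.5 ± 2.69 with IL-1b and 40.4 ± 2.45 with anti-CD3/CD28. Those of IL-1RI- cells were 35.3 ± 5.71, 33.0 ± 0.841 and 35.1 ± 2.25 M in the same order. Levels below are counts per M counts in the library after normalisation (CPM, mean ± SD, n = 3 per group). Changes are log2 fold changes ± standard error from edgeR, with p adjusted over the 18201 genes tested, and positions are on GRCh38. A gene named below as past the test moved the same way in 3 of 3 donors. The largest rises and falls are those among genes that met the naming rule, which asks for a mean of at least 5 CPM in a compared group.

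The first question was how the sorted populations differed without added IL-1b or anti-CD3/CD28 reagent. These were cultured cells, held overnight in 1 nM IL-2 before the sort and then for 9 h in media. In media, IL-1RI+ cells had more IL1R1, the gene for the sorted receptor (chromosome 2, 102064544 to 102179874), at 537 ± 43 against 21.2 ± 6.83 CPM, a log2 difference of 4.66 ± 0.27 (adjusted p = 5.78e-07). IL1R2, the decoy receptor for IL-1 (chromosome 2, 101991844 to 102028544), was higher by 5.76 ± 0.88 (10.7 ± 3.32 against 0.182 ± 0.161 CPM, adjusted p = 0.00545). FOXP3, the transcription factor of regulatory T cells (chromosome X, 49250436 to 49264826), was higher by 2.67 ± 0.48 (617 ± 106 against 96.8 ± 54.9 CPM, adjusted p = 0.011). LRRC32, which encodes the regulatory T cell surface protein GARP, was higher by 2.75 ± 0.64, and LAG3, an inhibitory receptor, by 2.63 ± 0.61 (adjusted p = 0.0412 and 0.0413). The other largest rises were CD300LD (4.69 ± 0.55), MACC1 (3.34 ± 0.78), the calcium-sensing receptor CASR (3.18 ± 0.62), LRP4 (3.15 ± 0.72) and the pseudokinase TRIB1 (2.48 ± 0.40). The largest falls were TENM1 (-3.60 ± 0.81), the leukotriene receptor CYSLTR1 (-3.47 ± 0.74), ST6GALNAC1 (-2.85 ± 0.54), CLU (-2.60 ± 0.45), GCNT4 (-2.50 ± 0.48), ACE (-2.48 ± 0.55), the IL-9 receptor IL9R (-2.45 ± 0.42), GCSAM (-2.33 ± 0.33), IGFBP3 (-2.30 ± 0.31) and SARDH (-2.28 ± 0.49). FOXP3 overlaps CCDC22 on the opposite strand, and CCDC22 itself did not pass (-0.58, adjusted p = 0.104).

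Of 14 regulatory T cell markers, 7 were higher in IL-1RI+ cells (FOXP3, LRRC32, IL1R2, CTLA4, IL2RA, TNFRSF1B and IKZF4). RTKN2, another marker, was lower (-1.58 ± 0.20). Adjusted over the list alone, 8 were higher and 2 lower (camera adjusted p = 4.44e-09, but adjusted p = 0.182 with an estimated correlation, and 0.0133 with an estimated correlation and the donor block). IL2RA, the high-affinity IL-2 receptor chain, was at 440 ± 44.2 against 137 ± 38.0 CPM. IL2RA and CTLA4 also belong to the list of T cell activation genes, of which 4 of 20 were higher, with LAG3 and HAVCR2. Adjusted over the list alone, 6 were higher and 2 lower (camera adjusted p = 0.000139; adjusted p = 0.315 with an estimated correlation). Of 25 cell cycle genes 4 were higher, namely TYMS (1.22 ± 0.23), CDC25A (1.08 ± 0.23), CDC6 (0.99 ± 0.23) and PCNA (0.70 ± 0.17). Adjusted over the list alone 20 were higher (camera adjusted p = 2.27e-19). Of 19 genes of the ATF4 amino acid response 5 were higher, among them ATF5 (1.94 ± 0.33), the serine synthesis enzyme PHGDH (1.48 ± 0.36), SHMT2 (0.88 ± 0.14) and the amino acid transporter SLC7A5 (0.73 ± 0.11). Adjusted over the list alone 11 were higher (camera adjusted p = 5.34e-12). ATF5 overlaps IL4I1 and NUP62 on the opposite strand, so its value is less certain. Of 18 cytokine STAT target genes 4 were higher, with OSM at 1.05 ± 0.21, IL2RB at 0.68 ± 0.14 and PIM1 at 0.38 ± 0.08 beside IL2RA (6 adjusted over the list alone, camera adjusted p = 9.51e-09). Of 19 Th17 lineage regulators and receptors 2 were higher, IL1R1 and CTSH (1.24 ± 0.22), and adjusted over the list alone 6 were (camera adjusted p = 7.35e-14). IL1R1 differs by the sort itself, and without it 1 of 18 was higher, 5 adjusted over the list alone (camera adjusted p = 8.97e-08). With an estimated correlation the camera adjusted p was 0.039 with IL1R1 and 0.178 without it. Without IL1R1 it was 0.0278 when the donor block was used as well.

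Glycolysis genes were higher in 3 of 20, ENO1 (0.85 ± 0.15), GAPDH (0.75 ± 0.18) and LDHA (0.66 ± 0.16), and in 6 adjusted over the list alone (camera adjusted p = 4.03e-07; adjusted p = 0.382 with an estimated correlation). All of these have near-identical pseudogene copies. In the IL-1 family list 3 of 19 were higher, IL1R2, IL1R1 and the IL-18 receptor IL18R1 (1.04 ± 0.24), also 3 adjusted over the list alone (camera adjusted p = 4.03e-07; adjusted p = 0.0966 with an estimated correlation). Without IL1R1 the camera adjusted p of this list was 0.0064 (0.391 with an estimated correlation). Of 10 Th2 markers IL17RB was lower (-2.05 ± 0.41), and adjusted over the list alone 5 were (camera adjusted p = 0.000148; adjusted p = 0.239 with an estimated correlation). PTGDR2, which encodes the Th2 receptor CRTH2, stood at -3.37 ± 0.85 (adjusted p = 0.0551, and 0.00184 with the donor block). Of 20 resting and central memory genes LEF1 was lower (-1.50 ± 0.29), and adjusted over the list alone 3 were (camera adjusted p = 0.0145; adjusted p = 0.406 with an estimated correlation). The 8 Th17 cytokines and chemokines showed no called member (camera adjusted p = 0.383), with IL26 at 0.62 ± 0.83 (adjusted p = 0.82) and CCL20 at 1.24 ± 0.60 (adjusted p = 0.341, and 0.0436 with the donor block). IL17A had 29 counts over the IL-1RI+ media libraries and 3 over the IL-1RI- ones, a ratio of 9.28 with a counting interval of 2.88 to 47.6. Intervals and floors of this kind cover counting error only. Of the sort markers, CCR6 (0.53 ± 0.17, adjusted p = 0.121) and CCR4 (0.43 ± 0.18, adjusted p = 0.26) passed with the donor block (0.0121 and 0.0105), while KLRB1, the gene for CD161, stood at 0.18 ± 0.27 and CXCR3 at -0.60 ± 0.96 (adjusted p = 0.849 and 0.859).

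Lists of markers of other cells were not called by camera here, although 1 of 9 follicular helper markers was lower over all genes, CXCR5 (-2.06 ± 0.46, adjusted p = 0.0358), which was picked after its value was seen. The camera adjusted p was 0.724 for B cells, 0.5 for monocytes and dendritic cells, 0.859 for MAIT, CD8 and gamma-delta T cells, 0.697 for Th1 and cytotoxic cells, 0.919 for follicular helper T cells and 0.17 for innate lymphoid and NK cells, the last 0.0283 with the donor block. Mitochondrially encoded mRNAs had a list median of -0.36 (camera adjusted p = 0.121, and 0.00353 with the donor block), and mitochondrial counts made up 2.48 ± 0.503% of IL-1RI+ and 3.07 ± 1.15% of IL-1RI- media libraries. The lists for other T cell cytokines, NF-kB targets, interferon response, unfolded protein response and replication-dependent histones were not called either (camera adjusted p = 0.992, 0.494, 0.327, 0.0615 and 0.0903). By the edgeR quasi-likelihood test, 215 genes were higher and 160 lower in IL-1RI+ than in IL-1RI- media cells, 375 in all. With the donor as a block the counts were 1318 and 1132, and with upper-quartile factors 166 and 171. Leaving out IL-1RI+ media replicate 1 or 2 gave 85 or 134 genes, and leaving out IL-1RI- media replicate 1, 2 or 3 gave 128, 138 or 119. These leave-outs were made in the fit without the donor, where differences between donors count as error. There, 6 of the 20 genes named for the largest differences passed without any single library (IL1R1, IL1R2, CD300LD, TRIB1, GCSAM and IGFBP3). Only 1 of them, IL1R1, passed there whichever donor was left out. FOXP3 did not pass there without IL-1RI- media replicate 1 or 3. In the fit with the donor block, 327, 285 and 295 of the 375 genes still passed without donor 1, 2 and 3.

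The second question was what IL-1b did to cells that carry its receptor. In IL-1RI+ cells, IL-1b raised IL22, a cytokine that acts on epithelia (chromosome 12, 68248242 to 68253604), from 0.516 ± 0.178 to 11.3 ± 3.88 CPM, a log2 change of 4.46 ± 0.67 (adjusted p = 0.00465). The NF-kB subunit genes RELB (chromosome 19, 45001430 to 45038198) and NFKB2 (chromosome 10, 102394110 to 102402529) rose by 2.37 ± 0.16 and 2.17 ± 0.13 (adjusted p = 8.66e-07 and 5.44e-07), NFKB2 from 97.9 ± 13.4 to 440 ± 28.5 CPM. RNF207, a RING finger gene (chromosome 1, 6205475 to 6221299), rose from 5.35 ± 1.82 to 56.9 ± 3.25 CPM (3.41 ± 0.23, adjusted p = 8.66e-07). It overlaps RPL22 and ICMT on the opposite strand, which stood at 0.10 and -0.04. IL26, an antimicrobial cytokine (chromosome 12, 68201351 to 68225821), stood at 1.83 ± 0.673 CPM with IL-1b and 0.846 ± 0.559 in media. Its change of 1.11 ± 0.79 was in the same direction in 3 of 3 donors but did not pass the test (adjusted p = 0.814, and 0.407 with the donor block). It overlaps the antisense RNA gene IFNG-AS1 on the opposite strand, which did not pass the count filter.

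**Figure D1:**
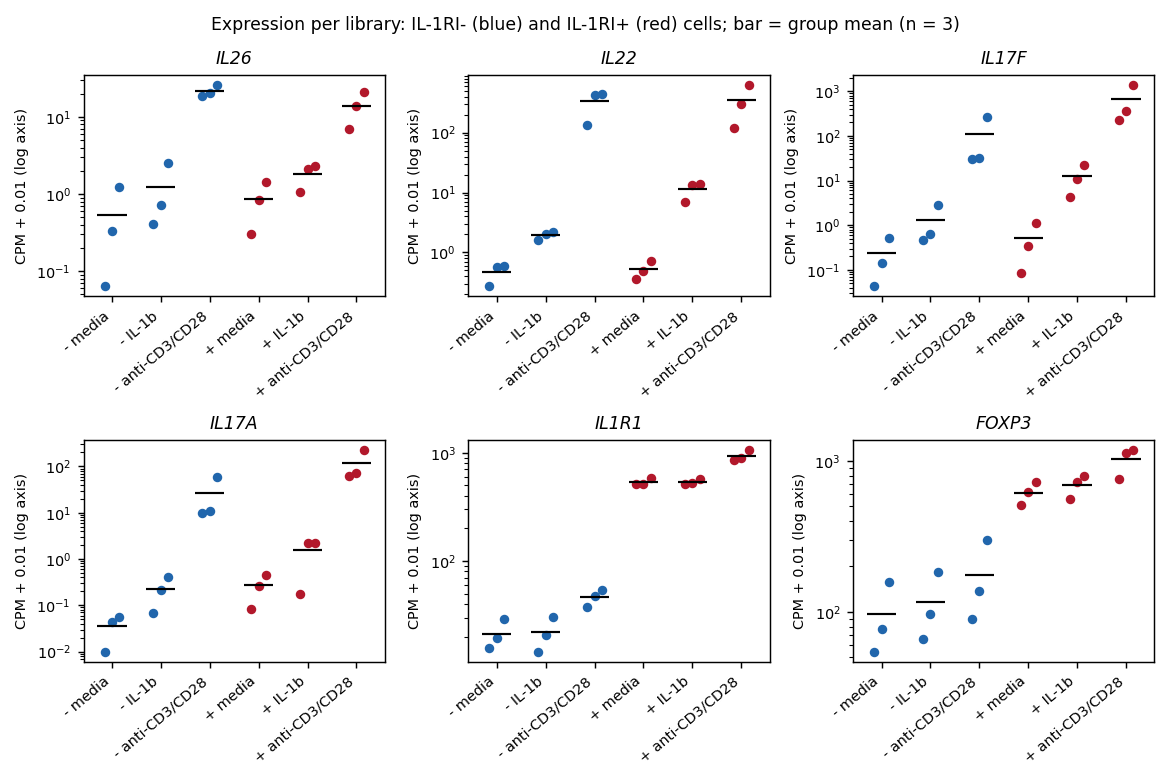
CPM plus 0.01 (log axis) of IL26, IL22, IL17F, IL17A, IL1R1 and FOXP3 in each of the 6 groups, with a point for each library, a bar for the group mean (n = 3), IL-1RI- cells in blue and IL-1RI+ cells in red. IL22 in IL-1RI+ cells went from a mean of 0.516 in media to 11.3 with IL-1b and 350.3 with anti-CD3/CD28, while IL26 went from 0.846 to 1.83 and 13.96.

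The other largest rises with IL-1b were IER3 (2.63 ± 0.36), the amino acid oxidase IL4I1 (2.60 ± 0.52), the collagen-binding integrin ITGA1 (2.51 ± 0.47), WNT10A (2.36 ± 0.36), the kinase SGK1 (2.06 ± 0.27) and the apoptosis inhibitor BIRC3 (2.03 ± 0.30). IL4I1 overlaps NUP62 on the same strand, and ITGA1 overlaps PELO, so reads of these genes may not be fully separable. How the counting treated such reads was not stated. The largest falls were PLXND1, a semaphorin receptor (-1.31 ± 0.25, from 77.3 ± 10.2 to 31.2 ± 4.67 CPM), VIPR1, a receptor for vasoactive intestinal peptide (-1.20 ± 0.24), SEMA6C (-1.07 ± 0.18), the clock output gene DBP (-0.97 ± 0.19) and the Wnt feedback gene AXIN2 (-0.91 ± 0.19). FBXL16 (-0.74 ± 0.15), STMN3 (-0.74 ± 0.12), the histone deacetylase gene HDAC5 (-0.69 ± 0.12), VAT1 (-0.68 ± 0.10) and NPDC1 (-0.67 ± 0.11) followed.

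Of 28 NF-kB target genes 16 rose and 0 fell with IL-1b, and adjusted over the list alone 20 rose (edgeR; camera adjusted p = 9.26e-106). Among them were NFKBIA (1.99), the RNase gene ZC3H12A (1.91), BCL3 (1.92) and ICAM1 (1.68). Of the 8 Th17 cytokines and chemokines IL22 rose, and adjusted over the list alone 5 did (camera adjusted p = 6.78e-09). IL17F (chromosome 6, 52236681 to 52244537) stood at 12.5 ± 9.24 against 0.507 ± 0.538 CPM (4.61 ± 1.23, adjusted p = 0.141, and 5.15e-06 with the donor block). CXCL8, a neutrophil chemokine, stood at 5.68 ± 1.81 (adjusted p = 0.261, and 0.0187 with the donor block). IL17A (2.56 ± 1.05), CSF2 (5.61 ± 2.19), CCL20 (0.72 ± 0.54) and IL21 (0.53 ± 0.57) did not pass (adjusted p = 0.471, 0.431, 0.841 and 0.949). Without the donor in the model 0 of 18 cytokine STAT target genes passed over all genes and 8 rose adjusted over the list alone (camera adjusted p = 8.67e-11). With the donor block, which takes up the pairing of libraries by donor, 7 and 12 rose. These 3 lists were also called with an estimated correlation in camera (adjusted p = 6.88e-06, 0.0306 and 0.00735), and among the lists called in IL-1RI+ cells under IL-1b they were the only ones. The other lists called by camera with its preset correlation are given next with both values.

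Of 24 other T cell cytokines LTA, the gene for lymphotoxin alpha, rose (1.75 ± 0.25, from 101 ± 22.5 to 338 ± 29.5 CPM), and 4 rose adjusted over the list alone (camera adjusted p = 6.78e-09; adjusted p = 0.0744 with an estimated correlation). Of 20 activation genes CD274, which encodes PD-L1, rose (1.43 ± 0.24), and 5 did adjusted over the list alone (camera adjusted p = 0.000138; adjusted p = 0.362 with an estimated correlation). With the donor block 7 rose over all genes. Of 19 IL-1 family genes the adaptor kinase gene IRAK2 rose (1.80 ± 0.28), and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.0266; adjusted p = 0.594 with an estimated correlation). Of 23 cholesterol synthesis genes SQLE rose (1.11 ± 0.23), and 4 did adjusted over the list alone (camera adjusted p = 1.21e-07; adjusted p = 0.362 with an estimated correlation). In the ATF4 amino acid response no gene passed over all genes and 5 of 19 did adjusted over the list alone (camera adjusted p = 3.48e-09; adjusted p = 0.0539 with an estimated correlation, and 0.0351 with the donor block as well). With the donor block 7 and 10 passed. The unfolded protein response had 0 of 20 genes over all genes and 4 adjusted over the list alone, and 2 and 13 with the donor block (camera adjusted p = 2.87e-09; adjusted p = 0.32 with an estimated correlation). The interferon response had 0 of 30 and 5, and 4 and 7 with the donor block (camera adjusted p = 0.00175; adjusted p = 0.447 with an estimated correlation) and the cell cycle 0 of 25 and 1, and 1 and 1 with the block (camera adjusted p = 0.0266; adjusted p = 0.626 with an estimated correlation). For the regulatory T cell markers both counts were 0 of 14, and 3 and 6 with the donor block (camera adjusted p = 0.0266; adjusted p = 0.626 with an estimated correlation).

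Lists without a camera call under IL-1b included the Th17 lineage regulators, of which BATF rose (1.12) and 3 of 19 did adjusted over the list alone (camera adjusted p = 0.124, with a list median of -0.04 and a mean of 0.10). The immediate early genes, of which JUNB rose (0.71), gave a camera adjusted p of 0.0806. Glycolysis (0.283), ribosome biogenesis (0.267), resting and central memory genes (0.144), Th1 (0.105), Th2 (0.144) and follicular helper markers (0.351) were not called, nor were heat shock genes (0.0521) or histones (0.706). Mitochondrially encoded mRNAs had a list median of -0.14 (camera adjusted p = 0.267, and 0.0432 with the donor block). Markers of B cells (0.542), monocytes and dendritic cells (0.454), MAIT, CD8 and gamma-delta T cells (0.901) and innate lymphoid and NK cells (0.994) were not called. The sort marker genes IL1R1 (0.00 ± 0.23), CCR6 (0.07 ± 0.17), CCR4 (-0.05 ± 0.18), KLRB1 (-0.27 ± 0.27) and CXCR3 (-0.14 ± 0.96) did not pass with IL-1b.

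By the edgeR test, 99 genes rose and 22 fell with IL-1b in IL-1RI+ cells, 121 in all. With the donor as a block 400 rose and 212 fell, 612 in all, but 354, 151 and 147 changed without donor 1, 2 and 3. In the fit without the donor, leaving out IL-1RI+ media replicate 1, 2 or 3 gave 69, 44 or 56 genes. Leaving out IL-1b replicate 1, 2 or 3 gave 60, 71 or 61. Of the 20 genes with the largest changes, 9 passed without any single library: IL22, RNF207, IER3, RELB, WNT10A, NFKB2, SGK1, BIRC3 and VAT1. In the same fit 3 passed whichever donor was left out, RNF207, RELB and NFKB2, while IL22, WNT10A, BIRC3 and VAT1 did not pass whichever donor was left out. With the donor block, 108, 76 and 83 of the 121 genes still passed without donor 1, 2 and 3.

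The same comparison in IL-1RI- cells asked whether cells sorted as lacking the receptor responded. RNF207 rose by 2.54 ± 0.22 (41.0 ± 11.0 against 7.06 ± 1.36 CPM, adjusted p = 5.17e-05). SGK1 rose by 1.69 ± 0.27, ZC3H12A by 1.59 ± 0.12, RELB by 1.58 ± 0.15 and NFKB2 by 1.53 ± 0.13 (adjusted p = 0.0206, 1.21e-05, 0.000145 and 4.76e-05). NFKBIA, the NF-kB inhibitor gene, also rose (1.52 ± 0.18). Of the NF-kB target genes 8 of 28 rose, and 18 did adjusted over the list alone (camera adjusted p = 5.41e-121). No Th17 cytokine passed over all genes or adjusted over the list alone, although camera called the list (adjusted p = 5.13e-08), with IL26 at 1.15 ± 0.82, IL22 at 2.0 ± 0.74 and IL17F at 2.38 ± 1.58 (adjusted p = 1 each). IL17A had 23 counts with IL-1b and 3 in media, a ratio of 8.17 with a counting interval of 2.47 to 42.5. Of the STAT target genes 0 of 18 passed either way in edgeR, and with the donor block 0 over all genes and 8 adjusted over the list alone (camera adjusted p = 1.12e-08). With an estimated correlation camera still called these 3 lists (adjusted p = 4.57e-06, 0.0347 and 0.0169 in the order NF-kB, Th17 cytokines, STAT). The fry test called NF-kB targets but not Th17 cytokines or STAT targets (adjusted p = 8.61e-05, 0.228 and 0.103), while with the donor block it called the latter pair too (0.0103 and 0.0114).

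Calls by camera were lost with an estimated correlation for other T cell cytokines (adjusted p = 0.232 with an estimated correlation), activation genes (0.232, and 0.0402 with the donor block as well), the IL-1 family (0.362), interferon response (0.615), cholesterol synthesis (0.541), ATF4 response (0.541), unfolded protein response (0.545) and regulatory T cell markers (0.541). In all, 22 genes rose and 0 fell in IL-1RI- cells by edgeR. At an unadjusted p under 0.05 there were 386 genes, of which 305 were higher and 81 lower. That is below a share of 0.05 of the genes tested, which unchanged genes alone would give, so the test was conservative. The fit leaves out the pairing by donor, so differences between donors count as error. With the donor block 888 genes had an unadjusted p under 0.05. The DESeq2 test gave 69 higher and 1 lower, and edgeR with the donor block 85 and 1, while edgeR on the compared groups alone with the donor block gave 618 and 460. Leaving out IL-1RI- media replicate 2 or 3 gave 13 or 9 genes, and leaving out IL-1b replicate 1 or 2 gave 13 or 12. SGK1 did not pass without IL-1RI- media replicate 2 or 3 or without IL-1RI- IL-1b replicate 1. Of the 5 genes named for the largest rises ZC3H12A alone passed whichever donor was left out in the fit without the donor. With the donor block, 16, 15 and 18 of the 22 genes still passed without donor 1, 2 and 3.

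Whether the response to IL-1b differed between the populations was tested as a difference of responses. No gene passed in edgeR, with 86 genes at an unadjusted p under 0.05. None passed in DESeq2 (89 at an unadjusted p under 0.05) or in edgeR with the donor block (328). Each count is below a share of 0.05 of the genes tested, which unchanged genes alone would give, so these tests were conservative. In simulations edgeR recovered 24.3% of differences of a log2 of 1, and 46.0% with the block. The lack of calls therefore does not show equal responses. With the donor, edgeR on the compared groups alone called 3 genes and DESeq2 called 1. All 99 genes raised in IL-1RI+ cells moved upward in IL-1RI- cells too, with a median log2 change of 0.81 against 1.12, and all 22 lowered genes moved downward (-0.33 against -0.68). Of the 22 genes raised in IL-1RI- cells, 19 were among those raised in IL-1RI+ cells, against 0.12 for independent lists. The difference for IL22 was 2.46 ± 1.06 and that for IL26 was -0.04 ± 1.09 (adjusted p = 1 for both). By camera the NF-kB target list ranked toward a larger response in IL-1RI+ cells than other genes did, with a median difference of 0.21, 0 of 28 genes past the threshold over all genes and 2 adjusted over the list alone, 7 with the donor block (camera adjusted p = 7.16e-22; adjusted p = 0.0147 with an estimated correlation). The fry test did not call this list (adjusted p = 0.5, and 0.206 with the donor block). Calls by camera on the difference that were lost with an estimated correlation were ATF4 response (camera adjusted p = 4.64e-09; adjusted p = 0.103 with an estimated correlation), unfolded protein response (1.59e-06; 0.566), other T cell cytokines (0.000219; 0.37), STAT targets (0.000227; 0.142) and Th17 cytokines (0.000769; 0.287). Cholesterol synthesis (0.00417; 0.792), glycolysis (0.0208; 0.829), interferon response (0.0321; 0.792) and Th1 markers (0.0431; 0.792) were lost in the same way. Mitochondrially encoded mRNAs were called with the donor block alone (camera adjusted p = 0.155, and 0.00705 with the block).

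**Figure D2:**
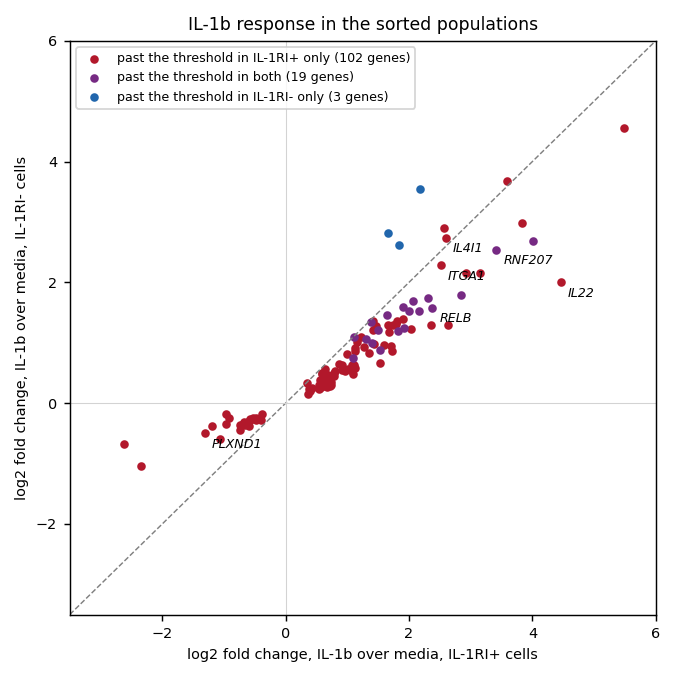
Log2 fold change with IL-1b against media in IL-1RI+ cells (x axis) and in IL-1RI- cells (y axis), with a point for each gene past the threshold in either population (n = 3 libraries per group) and a dashed line of equal change. The plot holds 19 genes past the threshold in both, 102 in IL-1RI+ cells alone and 3 in IL-1RI- cells alone. No gene passed the main edgeR test of the difference, which was conservative and does not show equal responses.

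The third question was how stimulation through CD3 and CD28 changed the same cells. In IL-1RI+ cells it raised IL17F by 10.35 ± 1.40 to 669 ± 647 CPM, IL17A (chromosome 6, 52186375 to 52190638) by 8.87 ± 1.12 to 120 ± 92.9 CPM and IL22 by 9.41 ± 0.75 to 350.3 ± 262 CPM (adjusted p = 2.07e-05, 1.02e-05 and 1.23e-07). IL26 rose by 4.05 ± 0.85 to 13.96 ± 7.09 CPM (adjusted p = 0.00102). IL10, an anti-inflammatory cytokine (chromosome 1, 206767602 to 206772494), rose by 9.97 ± 0.62, the granzyme gene GZMB by 9.53 ± 1.19 and the transcription factor genes ZBED2 and EGR2 by 9.15 ± 0.54 and 8.88 ± 1.47. ZBED2 (chromosome 3, 111592900 to 111595443) lies within CD96 on the opposite strand, which stood at -0.44. IGF2, an insulin-like growth factor, had no counts in the IL-1RI+ media libraries and 35.3 ± 23.1 CPM after stimulation, at least 1381-fold higher against a floor of 3 counts over the group. XIRP1 had 2 counts in media, a ratio of 1825 with a counting interval of 504.8 to 1.507e+04, and MAK had 1 count, a ratio of 653.9 with an interval of 116.9 to 2.587e+04.

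The largest falls were VSIG1 (-7.04 ± 0.81, from 36.6 ± 3.15 to 0.272 ± 0.419 CPM), PI16 (-6.85 ± 0.92), HKDC1 (-6.74 ± 1.01), AIRE (-6.65 ± 0.83), CR1 (-6.09 ± 1.03), RAP1GAP2 (-6.03 ± 0.59), PTGDS (-5.67 ± 0.83), SAMD3 (-5.40 ± 0.75), MAP2K6 (-5.38 ± 0.58) and TSPAN32 (-5.37 ± 0.95). PI16 marks a subset of memory T cells, and MAP2K6 encodes an activator of p38. Among the sort markers IL1R1 (0.80 ± 0.23), CCR6 (0.43 ± 0.17) and CCR4 (0.72 ± 0.18) rose, KLRB1 fell (-1.89 ± 0.28) and CXCR3 did not pass (-0.53 ± 0.97, adjusted p = 0.691).

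All 8 Th17 cytokines and chemokines rose, also adjusted over the list alone, among them CSF2 (8.26 ± 2.25), CCL20 (7.50 ± 0.66), IL21 (6.31 ± 0.55) and CXCL8 (5.87 ± 1.82). Camera called this list (adjusted p = 3.96e-05; adjusted p = 0.0921 with an estimated correlation, and 0.0124 with the donor block as well). Of 19 Th17 lineage genes 9 rose and 3 fell, the same adjusted over the list alone, with IRF4 (4.54 ± 0.30), BATF (3.34 ± 0.24) and IL23R (3.10 ± 0.34) rising most. Camera called the list with its preset correlation (adjusted p = 0.0057; adjusted p = 0.381 with an estimated correlation). Of 24 other T cell cytokines 16 rose and 1 fell, and 18 and 1 adjusted over the list alone (camera adjusted p = 5.27e-05; adjusted p = 0.174 with an estimated correlation). IFNG and IL4 had no counts in media and were at least 161-fold and at least 73.8-fold higher against the same floor, and the chemokine gene CCL3, which has near-identical copies, rose by 8.52 ± 1.54. NF-kB targets rose in 27 of 28, also 27 adjusted over the list alone, with IER3 (6.24 ± 0.41), IL4I1 (4.91 ± 0.57), ICAM1 (4.59 ± 0.26) and NFKBIA (4.17 ± 0.20) rising most. The camera adjusted p was 1.1e-40. Of 18 STAT target genes 14 rose and 3 fell, with IL12RB2 (5.53 ± 0.90), PIM3 (3.56 ± 0.28), SOCS3 (3.03 ± 0.34) and IL2RA (2.72 ± 0.23) rising most. The counts were the same adjusted over the list alone (camera adjusted p = 4.48e-08). The ATF4 response rose in 18 of 19, also adjusted over the list alone, led by CTH (3.90 ± 0.29), DDIT4 (3.38 ± 0.28) and SLC7A5 (2.51 ± 0.12). The camera adjusted p was 7.32e-15. These last 3 lists were the ones still called with an estimated correlation in IL-1RI+ cells (adjusted p = 0.000882, 0.017 and 0.0155).

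Immediate early genes rose in 22 of 24, and 23 adjusted over the list alone, with EGR3 at 8.14 ± 1.14, NR4A3 at 7.52 ± 0.96 and EGR4, with 1 count in media, at a ratio of 427 with an interval of 76.21 to 1.691e+04. Camera called the list (adjusted p = 6.94e-09; adjusted p = 0.158 with an estimated correlation, and 0.0404 with the donor block as well). Activation genes rose in 17 of 20 and fell in 1, the same adjusted over the list alone, led by TNFRSF9 (7.86 ± 1.28), TNFRSF8 (5.88 ± 0.80), CTLA4 (4.61 ± 0.51) and LAG3 (4.21 ± 0.63). Camera called them (adjusted p = 3.15e-08; adjusted p = 0.101 with an estimated correlation, and 0.0163 with the donor block as well). Ribosome biogenesis genes rose in 25 of 25, also adjusted over the list alone, with RRP12 at 2.54 ± 0.27 and NOP16 at 1.95 ± 0.16 (camera adjusted p = 1.11e-25; adjusted p = 0.0599 with an estimated correlation). Unfolded protein response genes rose in 19 of 20, and 20 adjusted over the list alone, with SEC11C at 1.77 ± 0.14 and the chaperone gene HSPA5 at 1.58 ± 0.18 (camera adjusted p = 9.28e-10; adjusted p = 0.174 with an estimated correlation). Cholesterol synthesis genes rose in 18 of 23 and fell in 1, the same adjusted over the list alone, with HMGCS1 at 3.54 ± 0.37 and CYP51A1 at 2.75 ± 0.31 (camera adjusted p = 2.34e-05; adjusted p = 0.381 with an estimated correlation). Glycolysis genes rose in 15 of 20 and fell in 1, and 16 and 2 adjusted over the list alone, with HK2 at 2.22 ± 0.28 and LDHA at 1.83 ± 0.17 (camera adjusted p = 0.000198; adjusted p = 0.458 with an estimated correlation). Heat shock genes rose in 7 of 12, also adjusted over the list alone, with HSP90AB1 at 2.01 ± 0.18 and HSPD1 at 1.98 ± 0.17 (camera adjusted p = 0.000107; adjusted p = 0.174 with an estimated correlation).

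Follicular helper markers rose in 7 of 9, also adjusted over the list alone, with CXCR5 at 3.18 ± 0.48 and ICOS at 3.12 ± 0.32 (camera adjusted p = 0.00119; adjusted p = 0.0599 with an estimated correlation, and 0.0296 with the donor block as well). Regulatory T cell markers rose in 9 of 14 and fell in 1, and 10 and 1 adjusted over the list alone, with CCR8 at 3.88 ± 0.99 and LRRC32 at 3.50 ± 0.64 (camera adjusted p = 0.00505; adjusted p = 0.487 with an estimated correlation). The IL-1 family rose in 10 of 19 and fell in 3, with IL1A at 6.44 ± 0.64, the receptor antagonist gene IL1RN at 5.65 ± 1.5 and the inhibitory receptor gene SIGIRR at -3.65 ± 0.17 (camera adjusted p = 0.151, and 0.0417 with the donor block). Resting and central memory genes fell in 9 of 20 and rose in 6 (camera adjusted p = 0.151), with KLF2, a regulator of T cell exit from tissue (chromosome 19, 16324817 to 16327874), falling from 1207 ± 219 to 31.3 ± 32.4 CPM (-5.27 ± 0.75). Interferon response genes rose in 6 of 30 and fell in 12 (camera adjusted p = 0.348), with IFIT2 at -2.79 ± 0.46. Th1 and cytotoxic markers rose in 7 of 17 and fell in 1 (camera adjusted p = 0.164), with TBX21 at 5.17 ± 0.92. Cell cycle genes rose in 3 of 25 and fell in 2 (camera adjusted p = 0.635, upward, with a list median of -0.11), with the cyclin gene CCND2 at 1.48 ± 0.13 and TOP2A at -1.41 ± 0.54. All 4 tested B cell markers fell, CD79B from 45.0 ± 5.06 to 8.60 ± 3.18 CPM (camera adjusted p = 0.0532, and 0.0113 with the donor block). Histone genes, which took at most 0.00611% of a library, fell in 3 of 8 (0.156) and monocyte and dendritic cell markers in 2 of 9 (0.413). Th2 markers (2 of 10 rose, 0.778), MAIT, CD8 and gamma-delta markers (2 of 10 fell, 0.635), innate lymphoid and NK markers (1 rose and 1 fell of 7, 0.893) and mitochondrial mRNAs (0 of 13, 2 fell with the donor block, 0.893) were not called by camera.

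In all, 4501 genes rose and 4466 fell with anti-CD3/CD28 in IL-1RI+ cells. With upper-quartile factors the median log2 change over all genes was -0.23, against -0.07 with the main scaling, and the split was 3581 to 5551, so changes are relative to the scaling. Each of the 20 genes with the largest changes passed without any single library and without any donor.

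**Figure D3:**
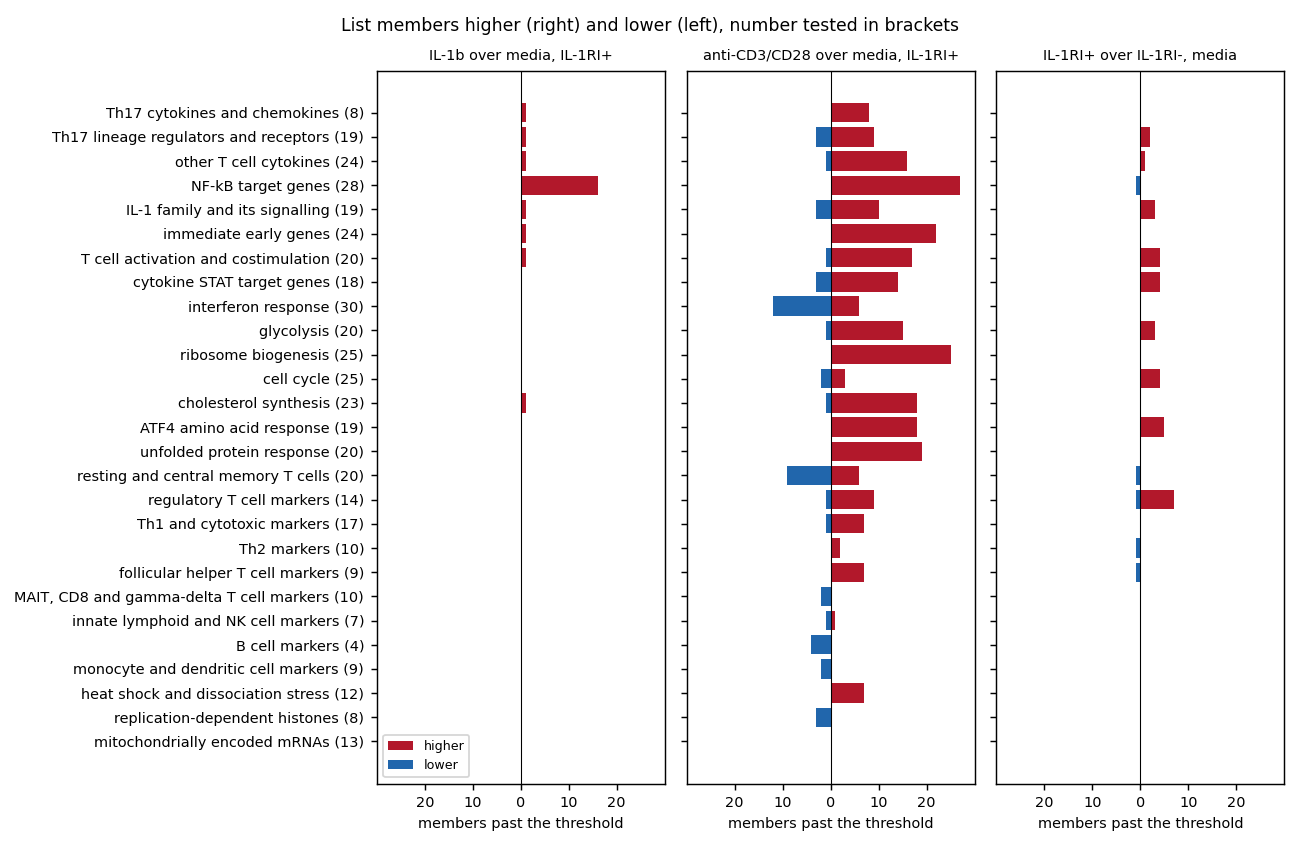
Number of genes of each fixed list past the threshold (x axis, genes), higher to the right and lower to the left, for IL-1b and for anti-CD3/CD28 in IL-1RI+ cells and for IL-1RI+ against IL-1RI- cells in media (n = 3 libraries per group). Of 28 NF-kB targets 16 rose with IL-1b and 27 with anti-CD3/CD28, while of 25 ribosome biogenesis genes 0 and 25 did.

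In IL-1RI- cells the reagent raised IL10, with 1 count in media, by a ratio of 5914 with an interval of 1061 to 2.336e+05, and IL17A, with 3 counts, by 978.6 with an interval of 334.5 to 4748. IL9 rose by 10.45 ± 1.39, ZBED2 by 9.85 ± 0.57 and IL22 by 9.44 ± 0.76 (adjusted p = 2.21e-05, 1.56e-08 and 1.94e-07). IL26 rose by 5.30 ± 0.91, from 0.532 ± 0.608 to 21.7 ± 3.92 CPM (adjusted p = 0.000223), and IL17F by 8.78 ± 1.41. IL1R1 rose by 1.11 ± 0.24 to 46.1 ± 7.90 CPM (adjusted p = 0.00144). AIRE (-4.89 ± 0.74), RAP1GAP2 (-4.79 ± 0.55), the ephrin receptor gene EPHA4 (-4.75 ± 0.45), CR1 (-4.46 ± 0.88) and DPEP2 (-4.28 ± 0.55) fell most. CXCL8 was the member of the Th17 cytokine list that did not pass (2.38 ± 1.52, adjusted p = 0.227, and 0.0517 with the donor block). CCR6 passed with the donor block (0.37 ± 0.17, adjusted p = 0.0877, and 0.0198 with the block).

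In IL-1RI- cells 6 lists were still called with an estimated correlation: Th17 cytokines (7 of 8 rose, adjusted p = 0.0482), NF-kB targets (27 of 28, 0.00137), STAT targets (14 rose and 1 fell of 18, 0.00357), ribosome biogenesis (25 of 25, 0.0414), the ATF4 response (19 of 19, 0.00817) and follicular helper markers (8 of 9, 0.0258). Camera calls lost with an estimated correlation covered Th17 lineage genes (adjusted p = 0.261 with an estimated correlation), other T cell cytokines (0.0535), the IL-1 family (0.394), immediate early genes (0.115), activation genes (0.0535), glycolysis (0.261), cholesterol synthesis (0.249) and the unfolded protein response (0.229). They also covered resting and central memory genes (0.39; camera adjusted p = 0.0495, and 0.154 with the donor block), regulatory T cell markers (0.39), B cell markers (0.229) and heat shock genes (0.0877). With the donor block as well as an estimated correlation, other T cell cytokines, immediate early genes and activation genes were called (adjusted p = 0.0354, 0.0321 and 0.0072). Th1 markers were called by camera with the donor block alone (adjusted p = 0.0607, and 0.0249 with the block).

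In all, 4040 genes rose and 4036 fell in IL-1RI- cells (3238 and 4975 with upper-quartile factors, with a median over all genes of -0.19 against -0.05). Of these, 3650 rising and 3430 falling genes were shared with IL-1RI+ cells, against 999 and 990 for independent lists, and 2 genes passed in opposite directions. The response to anti-CD3/CD28 differed between the populations for 4 genes in edgeR. IL23A, which encodes the IL-23 subunit p19 (chromosome 12, 56334174 to 56340410), rose more in IL-1RI+ cells, by 1.43 ± 0.17 (adjusted p = 0.0118), and PXK (chromosome 3, 58332880 to 58426126) by 0.995 ± 0.15 (adjusted p = 0.0466). TRERF1 (chromosome 6, 42224931 to 42452051) fell further in IL-1RI+ cells, with a difference of -1.47 ± 0.19 (adjusted p = 0.0159), and BTBD11 (chromosome 12, 107318413 to 107659642) differed by -1.61 ± 0.24 (adjusted p = 0.0466). The difference for IL26 was -1.26 ± 1.11 (adjusted p = 1). The camera test on the difference called interferon response (median -0.44, adjusted p = 1.66e-10; adjusted p = 0.157 with an estimated correlation), NF-kB targets (median 0.27, 2.31e-09; 0.157) and the unfolded protein response (0.00027; 0.986). With the donor block 108 genes differed, but 15, 7 and 19 without donor 1, 2 and 3. In the fit without the donor, leaving out 1 library gave 31 genes without IL-1RI- anti-CD3/CD28 replicate 2 and 52 without IL-1RI+ anti-CD3/CD28 replicate 3. It gave 2 without IL-1RI+ media replicate 3 and 1 without IL-1RI- media replicate 1. It gave 0 without IL-1RI+ media replicate 2, IL-1RI+ anti-CD3/CD28 replicate 1 or 2, IL-1RI- media replicate 2 or 3 or IL-1RI- anti-CD3/CD28 replicate 3, so no gene of the 4 passed throughout.

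The last question was how IL-1b and anti-CD3/CD28 compared in IL-1RI+ cells. Genes lowered by the reagent were the highest with IL-1b in relative terms: PI16 (6.54 ± 0.91), HKDC1 (6.52 ± 1.00), AIRE (6.44 ± 0.82), VSIG1 (6.35 ± 0.80) and RAP1GAP2 (5.88 ± 0.58). ZBED2 (-8.92 ± 0.53), IL10 (-8.64 ± 0.55), GALR2 (-8.45 ± 1.32) and XIRP1 (-8.28 ± 1.54) were the lowest with IL-1b, as was CXCL9, an interferon-induced chemokine with 1 count under IL-1b, at a ratio of 0.000828 with an interval of 2.09e-05 to 0.00462. Of these 10 genes, CXCL9 did not pass when replicate 1 was left out. IL17A (-6.31 ± 0.95), IL17F (-5.74 ± 1.09), CCL20 (-6.78 ± 0.63) and IL21 (-5.78 ± 0.53) were among 6 of 8 Th17 cytokines lower with IL-1b than with the reagent (camera adjusted p = 0.000361; adjusted p = 0.127 with an estimated correlation, and 0.018 with the donor block as well). NF-kB targets were lower with IL-1b in 24 of 28 and higher in ZC3H12A alone (camera adjusted p = 1.04e-19). With an estimated correlation the call held for NF-kB targets (adjusted p = 0.025), STAT targets (3 higher and 12 lower of 18, 0.0423), ribosome biogenesis (25 of 25 lower, 0.0423), the ATF4 response (18 of 19 lower, 0.0355) and follicular helper markers (7 of 9 lower, 0.0423).

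Camera calls lost with an estimated correlation covered immediate early genes (adjusted p = 0.119 with an estimated correlation, and 0.0235 with the donor block as well), activation genes (0.119, and 0.0213 with the block as well), other T cell cytokines (0.292), Th17 lineage genes (0.451), glycolysis (0.451), cholesterol synthesis (0.527), the unfolded protein response (0.292), regulatory T cell markers (0.533), B cell markers (0.211) and heat shock genes (0.211). Interferon response genes were higher with IL-1b in 12 of 30 and lower in 3 (camera adjusted p = 0.032, and 0.125 with the donor block; adjusted p = 0.527 with an estimated correlation). In all, 4019 genes were higher and 3953 lower with IL-1b than with the reagent, and with upper-quartile factors 4907 and 3164 (median over all genes 0.19 against 0.07).

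Of the 99 genes raised by IL-1b in IL-1RI+ cells, 88 were also raised by anti-CD3/CD28 (24.5 for independent lists), and of the 22 lowered genes 21 were also lowered (5.40 for independent lists), 109 in all. With the donor block the counts were 338 and 194, 532 in all. Both comparisons share the media libraries. In 20 simulations of unchanged groups against shared media, 0 genes passed in both comparisons. No gene was changed in them, so hardly any could pass in either, and this 0 is no baseline for the 109. What shared media add to the overlap of truly changed genes was not simulated. The correlation of log2 changes across genes averaged 0.497 (0.471 to 0.523) in the simulations and was 0.536 in the data. These correlations are not comparable, since the simulated changes hold noise alone while many genes changed in the data. The covariance was 0.357 in the data and 0.0604 in the simulations. Genes are not independent replicates. The media groups hold 3 libraries each and were not divided into separate controls.

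**Figure D4:**
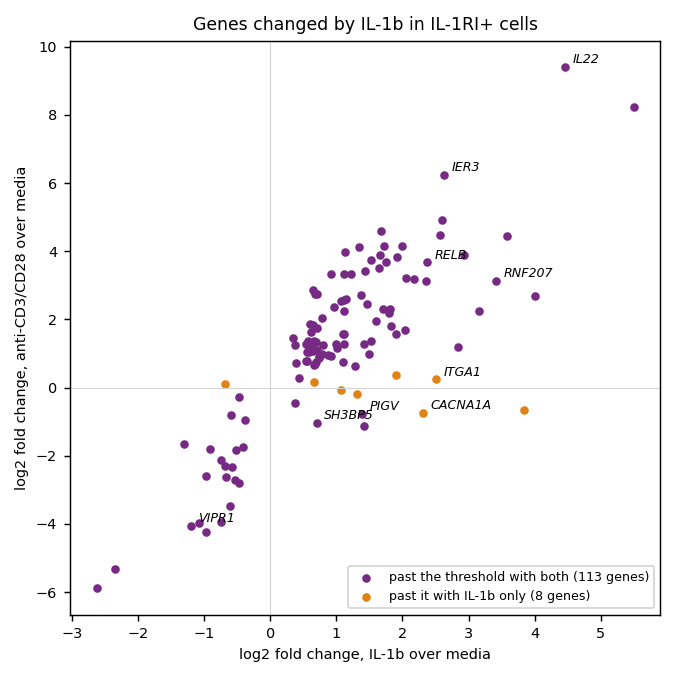
Log2 fold change with IL-1b (x axis) and with anti-CD3/CD28 (y axis), each against media, in IL-1RI+ cells, with a point for each of the 121 genes past the threshold with IL-1b (n = 3 libraries per group). Of these, 113 also passed with anti-CD3/CD28, in either direction, and 8 did not, and PIGV, ITGA1 and CACNA1A lie among the genes not raised by the reagent.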

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

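Every explanation test in this part was chosen only after the result was seen; the splits of the libraries were planned.

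IL23A was picked because its response to anti-CD3/CD28 differed between the populations, by 1.43 on the log2 scale: it rose by 2.74 in IL-1RI+ and by 1.31 in IL-1RI- cells. PXK was picked for the same reason, with a difference of 0.995 and rises of 1.61 and 0.61. TRERF1 differed by -1.47, with changes of -2.19 in IL-1RI+ and -0.73 in IL-1RI- cells. BTBD11 differed by -1.61, with -1.43 in IL-1RI+ cells and 0.19 in IL-1RI- cells, the latter not past the threshold (adjusted p = 0.411).

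Genes rose with IL-1b in cells sorted as lacking its receptor, 22 of them in edgeR. Carry-over of IL-1RI+ cells into the IL-1RI- sort is argued against, since over these 22 genes the rise in IL-1RI- cells was a median of 64.4% of that in IL-1RI+ cells (10th percentile 45.9%), while IL1R1 in IL-1RI- media cells was 3.95% of its IL-1RI+ level and at most 5.60% in any donor. Over all 99 genes raised in IL-1RI+ cells the median was 55.0%. Cells with little surface IL-1RI within the IL-1RI- gate stay open: IL1R1 averaged 21.2 CPM in IL-1RI- media libraries, which such cells may explain, but a test of bulk RNA does not separate a low level in all cells from a high level in a few. Signalling from a few responding cells to their neighbours was not tested.

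Of 14 regulatory T cell markers, 7 were higher and 1 lower in IL-1RI+ than in IL-1RI- cells in media (camera adjusted p = 4.44e-09, but not called with an estimated correlation, adjusted p = 0.182). Activation of the kind the anti-CD3/CD28 reagent gives stays open. Of the 7 list members called higher, 4 (FOXP3, IKZF4, IL1R2 and TNFRSF1B) differed by more than IL-1RI- cells responded to the reagent. FOXP3 differed by 2.67 ± 0.48 against a response of 0.86 ± 0.45, and IL1R2 by 5.76 ± 0.88 against 3.95 ± 0.87. This cannot decide the question: the members were chosen for being higher, the gaps were not tested, and a response at 9 h sets no upper bound for longer activation. The other 3 (IL2RA, CTLA4 and LRRC32) lay below that response. A share of regulatory T cells within the IL-1RI+ sort stays open: the list median was 1.14, but RTKN2, another of its markers, was lower. Whether the sort on CCR6, CD161, CCR4 and CXCR3 kept or removed such cells was not tested. Expression of these genes by IL-1RI+ Th17 cells themselves also stays open and was not tested.

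IL26 was higher with IL-1b in IL-1RI+ cells in 3 of 3 donors without passing the threshold. Too few reads is argued against, since 215 counts with IL-1b against 95 in media gave a ratio of 2.19 with a lower counting bound of 1.71. Differences between donors in IL26 level stay open as a cause of the wide error: with the donor in the model the standard error went from 0.79 to 0.66 and the adjusted p from 0.814 to 0.407 (unadjusted 0.181 and 0.109). A change in IL-26 secretion without a change in its RNA was not measured by these data.

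For each comparison the 6 libraries compared, or the 6 pairs behind a difference, make 10 splits, too few for a share under 0.05. Every split but the real one mixes the compared groups, so a real difference enters its spread. A count of 0 in such a split therefore carries little information. As many genes were called in 1 of the 10 splits, the real one, for IL-1b in IL-1RI+ cells (121 genes, highest other 0), IL-1b in IL-1RI- cells (22, 0), anti-CD3/CD28 in IL-1RI+ cells (8967, 0) and in IL-1RI- cells (8076, 0), the populations in media (375, 0) and IL-1b against anti-CD3/CD28 (7972, 0). For the difference in the IL-1b response 10 of the 10 splits gave as many, since all gave 0. For the difference in the anti-CD3/CD28 response 2 of the 10 splits gave as many, with 4 genes in the real split and 20 in the highest other. That split does not part every donor's pair, as the real one does. The other splits that do not part every pair gave 0, and the cause of the larger count was not tested. Among the 4 splits that part all pairs the highest other was 0. With the donor block 108 genes were called, but 15, 7 and 19 without donor 1, 2 and 3.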

How the results depend on the processing

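Which tests used the donor together with another choice, the leave-outs in the fit with the donor, and the removal of IL1R1 from lists were decided only after the results were seen; the other alternatives were planned. Of 385 results for single genes, 384 kept direction and side of the threshold with DESeq2 size factors, 374 with upper-quartile factors, 380 of 384 with the DESeq2 test and 379 with the donor block. All 378 with a value without the technical genes did, and 302 of 384, 303 and 304 did without donor 1, 2 and 3. The pooled counts hide differences between comparisons. Of the genes named for the largest changes with anti-CD3/CD28, 20 of 20 in IL-1RI+ and 10 of 10 in IL-1RI- cells passed whichever donor was left out. For IL-1b these were 3 of 20 and 1 of 5. They were 1 of 20 for the populations, 9 of 10 for IL-1b against anti-CD3/CD28 and 0 of 4 for the difference in the anti-CD3/CD28 response. Directions reversed for KLRB1 between the populations in media without replicate 1 (-0.00767, leave-outs up to 0.375) and for CXCR3 without replicate 2 (0.61) or without IL-1RI- media replicate 2 (0.85, leave-outs down to -1.26). Of 37 list calls for IL-1b and anti-CD3/CD28 in IL-1RI+ cells and the populations in media, 37 were kept with DESeq2 size factors and 37 with the block, 10 with an estimated correlation, 16 with an estimated correlation and the block, and 26 with fry. In other comparisons the block ended the calls of resting and central memory genes with anti-CD3/CD28 in IL-1RI- cells (0.0495 to 0.154) and of interferon response between IL-1b and anti-CD3/CD28 (0.032 to 0.125).

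For IL-1b in IL-1RI+ cells the main count was 121; the replicate block gave 612, the DESeq2 test 367, DESeq2 with the block 1092, the compared groups alone 62 and with the block 3220, a log2 change of at least 1 gave 63, and leaving out donors or single libraries gave 10 to 71. For IL-1b in IL-1RI- cells (22) the same settings gave 86, 70, 148, 4 and 1078, no filter gave 33, and leave-outs gave 1 to 26. For anti-CD3/CD28 a log2 change of at least 1 gave 4647 in IL-1RI+ cells (8967) and 3802 in IL-1RI- cells (8076), where leave-outs gave 5139 to 7643, the lowest without replicate 2. For the populations in media (375) the replicate block gave 2450, DESeq2 1134, DESeq2 with the block 2970, the groups alone 149 and with the block 3179, a log2 change of at least 1 gave 174, and leave-outs gave 21 to 263. For IL-1b against anti-CD3/CD28 (7972) a log2 change of at least 1 gave 3746. For the difference in the IL-1b response (0) DESeq2 with the block gave 1 gene, IL3, and the groups alone with the block gave 3, CACNA1I, DPEP2 and VIPR1. The IL3 estimate was a log2 difference of 21.9 ± 4.31, too large to be read as a size of response. IL3 passed in no other setting. For the difference in the anti-CD3/CD28 response (4) the block gave 108, DESeq2 110, DESeq2 with the block 556, no filter 9, the groups alone 0 and with the block 8, and leave-outs gave 0 to 52. The overlap of IL-1b and anti-CD3/CD28 calls (109) was 532 with the block, 318 with DESeq2, 52 with a log2 change of at least 1 and 9 to 29 without a donor. Leaving out donor 1, 2 or 3 also lowered counts in the block fit. There it gave 354, 151 or 147 for IL-1b in IL-1RI+ cells and 42, 25 or 38 for IL-1b in IL-1RI- cells. For the populations in media it gave 1264, 984 or 1026.

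The donor block raised each of the counts it moved because it removed the donor differences from the error, the dispersion falling from 0.115 to 0.0178. It also raised the number of called members in many lists, for IL-1b in IL-1RI+ cells from 0 to 7 of the STAT targets. A log2 minimum asks for more, so its counts fall by construction. Leave-outs leave 2 libraries in a group or fewer donors, and most of their counts fell. Some rose, from 4 to 52 and 31 for the difference in the anti-CD3/CD28 response and from 22 to 26 for IL-1b in IL-1RI- cells; the cause of these and the other moves was not tested. IL21, IL17A and IL26 had few counts in media, and their changes with IL-1b had standard errors of 0.57, 1.05 and 0.79; these errors alone do not part depth from the spread between donors, and for IL26 too few reads is argued against.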

Other observations

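The genes of this part were chosen after their values were seen. Some genes rose with IL-1b but not with anti-CD3/CD28 in IL-1RI+ cells. There were 11 of them, and 4 of the 11 fell with the reagent. All 11 passed the threshold in the comparison of the treatments, which the choice of these genes favours, since it rests on the same libraries. PIGV, an enzyme of GPI anchor synthesis, rose from 27.9 to 73.5 CPM with IL-1b (1.40 ± 0.09, adjusted p = 8.66e-07) and fell to 16.3 with the reagent (-0.78 ± 0.09, adjusted p = 6.31e-06), a difference of 2.17 ± 0.10 (adjusted p = 3.59e-09). SH3BP5, a regulator of JNK and RAB11, changed by 0.71 and -1.03, and SH2D3C, an adaptor, by 0.37 and -0.46. The calcium channel gene CACNA1A rose by 2.31 with IL-1b and stood at -0.74 with the reagent (adjusted p = 0.0554), a difference of 3.05 ± 0.32. The integrin gene ITGA1 rose by 2.51 with IL-1b and stood at 0.24 with the reagent, a difference of 2.27 ± 0.47 (adjusted p = 0.00104). Its rise with IL-1b did not pass when any of 5 single libraries or any donor was left out. ABAT, a GABA-degrading enzyme, and UNC119 rose by 1.31 and 1.90 with IL-1b against -0.19 and 0.37. The others were TMTC2, TSPOAP1-AS1, AC010247.1 and AL391056.1, of which AC010247.1 fell with the reagent.

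In IL-1RI- cells, 3 genes passed with IL-1b that did not pass in IL-1RI+ cells. ABTB2 rose by 3.54 ± 0.60 (2.18 in IL-1RI+ cells), the lipid transporter gene MFSD2A by 2.82 ± 0.46 (1.66) and PDZD2 by 2.62 ± 0.42 (1.84). Their adjusted p was 0.0279, 0.0229 and 0.0206 in IL-1RI- and 0.1, 0.129 and 0.0615 in IL-1RI+ cells, and the test of the difference between populations gave an adjusted p of 1 for each. IL1R2, which encodes the decoy receptor, rose with anti-CD3/CD28 in IL-1RI+ cells from 10.7 ± 3.32 to 101 ± 52.3 CPM (3.25 ± 0.68) and stood at 7.53 ± 4.36 CPM with IL-1b.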
